A study of Mus musculus with 16 samples.

How the data were processed

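The series holds ATAC-seq and CUT&RUN of mouse embryonic fibroblasts infected with Gfp, Atoh1, Pou4f3 or both Atoh1 and Pou4f3. Each of the 16 libraries has 1 peak list, and the labels gave each its infection, its antibody target where there was one, and its replicate number. ATAC-seq was deposited for 4 groups and CUT&RUN for 4 groups, with 2 libraries in each. Per the labels' protocols, ATAC libraries were made from nuclei with Tn5 transposase and amplified by PCR, and CUT&RUN fragments were purified with phenol and chloroform. The files are in the narrowPeak layout. Per the submitters' processing notes, the genome build was mm10 and the tools Bowtie2, MACS2, STAR and UMI-tools were used; their versions, roles and settings, read filters, and whether an antibody-free control entered peak calling are not given in the sources used here. Peaks were called per library, since the authors deposited 1 list per sample with different peaks in each.

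The authors' lists give for each peak a fold enrichment at the summit, which is a ratio within 1 library. They also give the deposited −log10 p-value and −log10 q-value of the peak caller for each peak, and a score that equals 10 times the deposited −log10 p, rounded down. Every list reached down to a −log10 p of about 2, so the authors' lists also hold weak peaks; 29.2% to 55.3% of the peaks of a library had a −log10 q of at least 5. ATAC lists repeat an interval once per summit, and such intervals were counted once. Fold enrichment and score are the authors' and were used only to describe, rank or filter peaks within a list. No read counts are given, so the depth of each library is unknown, accessibility could be compared only as presence or absence of a peak, and no intervals from counts could be made. A longer list holds weaker peaks, and this was examined with lists of equal length.

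Peaks on chromosomes 1 to 19, X and Y were used. Peaks of the libraries compared were merged where they overlapped by at least 1 bp. A region was gained when both libraries of a group had a peak in it and neither library of the other group did, and lost in the reverse case; regions with a peak in only some libraries of a group entered neither count. A site of a factor is a merged region with a peak in both replicates. A site was called closed when neither Gfp ATAC library had a peak overlapping it, and open in an infection when both ATAC libraries did. As background, regions or sites were moved by 20 kb and counted again. With 2 libraries per group an exact permutation test across libraries cannot reach a p of 0.05, the smallest two-sided p being 0.333. Tests that assume normal values were not used with so few libraries. Gains and losses were therefore set beside the same counts in the 2 splits that put 1 library of each group on each side. These measure replicate noise, meaning noise that differs between the replicates of a group. Anything both replicates of a group share besides the infection is not measured by them. Shares carry a standard error from leaving out each of 21 chromosomes in turn (block jackknife), which measures variation along the genome and not between cultures, and the value of each replicate. Classes of sites were compared by odds ratios with 95% confidence intervals, sites not being replicates. Overlaps of gains or of losses between infections share the Gfp libraries. They were set beside the product expected of independent lists and beside the mean of 20 simulations of unchanged groups. In these simulations all ATAC libraries, Gfp included, were drawn from 1 distribution, and list sizes were not matched to those observed.

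Gene positions came from an annotation of assembly GRCm38.p6, the same build as mm10; 21.5% of the regions of both Gfp libraries lay within 1 kb of a gene end, against 6.45% after the shift. The annotation used here has no strand, exons or sequence, so distances were taken to either end of the gene in place of the transcription start, positions are given as inside or outside a gene, and the motif comparisons fixed beforehand were not run. The groups, main comparisons, gene lists, named-gene rule and alternatives were fixed before the data were examined. Named genes were Atoh1, Pou4f3 and Gfi1; for gained, lost and double-only ATAC regions and gained ATOH1 sites the genes nearest, within 50 kb, to the 10 regions of highest rank, the rank being the lower of the percentiles of fold enrichment in both replicates, with at most 3 regions without a gene given by position; and for each gene list the 4 members with the highest ranked region. The same rule was applied, after the data were seen, to lost ATOH1 sites and to gained and lost POU4F3 sites, and not all genes it picked are named; some are not reported here. The 15 lists were hair cell, Merkel cell, pan-neuronal, Notch pathway, cerebellar granule precursor, intestinal secretory, sensory neuron (POU4F), skeletal muscle, epithelial, macrophage, endothelial, fibroblast, cell cycle, interferon response and housekeeping genes. Of their members, 331 matched the annotation, with repeats, and 2 did not (Mx1 and Mx2). For each list, members with at least 1 region within 50 kb were counted and tested against the 21887 protein-coding genes within bins of the number of ATAC regions of any library in the window. An exact hypergeometric test within bins took the place of the 100000 random lists fixed beforehand, of which it is the limit, with Benjamini-Hochberg adjustment over 165 tests. A count of regions in place of members, tested with 100000 random lists, was added after the data were seen.

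The alternatives were peaks with a −log10 q of at least 5, sharing by summits within 200 bp, lists of equal length (107886 intervals in ATAC and 74436 in CUT&RUN), sites of the other factor left out, regions near gene ends left out, gene windows of 10 kb or the nearest gene within 100 kb, the replicate number as a block, and each library left out in turn. The code that calls gained and lost regions was checked on simulated data built from the first Gfp list of 107886 intervals. Of 5000 gained regions 81.4% were recovered and of 3000 lost ones 80.2%, with 771 and 818 called without having been simulated. The 81% that could be detected was set by the simulation, in which libraries missed peaks independently. Detection in the real libraries was not estimated, so these values check the code and do not measure recovery in these data. Of random gene lists, 4.2% had a p under 0.05 in the list test, with region numbers and hits per gene drawn at random and not taken from the peak lists. This too checks the code and not the test on these data. A loss beside a peak that stays can be hidden by merging. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks on other contigs were left out of every comparison, and no gene expression was analysed here.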

Results

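Mouse embryonic fibroblasts, connective tissue cells grown from embryos, were infected with Gfp as a control, with Atoh1, with Pou4f3, or with Atoh1 and Pou4f3 together (the double infection). ATOH1 is a basic helix-loop-helix transcription factor of inner ear hair cells, Merkel cells, cerebellar granule cell precursors and intestinal secretory cells, and POU4F3 is a POU homeodomain factor of hair cells and Merkel cells. Accessible chromatin was mapped by ATAC-seq in all 4 infections, and binding of the factors by CUT&RUN, in which an antibody directs a nuclease to the sites of a protein. The CUT&RUN libraries held ATOH1 in the Atoh1 and the double infection and POU4F3 in the Pou4f3 and the double infection. Each of the 8 groups had n = 2 libraries, 16 in all. The ATAC peak lists held 107886 and 109020 intervals in Gfp cells, 123800 and 137280 in Atoh1 cells, 112174 and 119871 in Pou4f3 cells, and 138150 and 137945 in the double infection. The CUT&RUN lists held 88475 and 106435 ATOH1 peaks in Atoh1 cells, 122066 and 74436 ATOH1 peaks in the double infection, 145045 and 126851 POU4F3 peaks in Pou4f3 cells, and 137012 and 122812 POU4F3 peaks in the double infection. Read depth is unknown, since the lists give no counts. The Jaccard index of replicates averaged 0.592 in ATAC (0.577 to 0.622) and 0.326 in CUT&RUN (0.281 to 0.366), so that CUT&RUN sites carried the larger replicate error. Nothing in the labels states that replicates were separate cultures, so the spread between them may be technical.

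The infected genes were examined first in every library. ATAC peaks covered 41.9% and 45.8% of the Pou4f3 gene (chromosome 18, 42394597 to 42396093, mm10) in Gfp cells and 41.8% and 42.2% in Atoh1 cells, against 77.2% and 74.6% in Pou4f3 cells and 81.8% and 72.5% in the double infection. All 4 libraries labelled as Pou4f3-infected stood above the other 4. Part of that coverage lies on the gene body, where reads of an introduced cDNA can also align. Regions gained near Pou4f3 but outside the gene were at 42382942 to 42383526, 42393140 to 42393398 and 42416632 to 42417247 in Pou4f3 cells. Each overlapped a POU4F3 site of the same cells (42382400 to 42383346, 42393002 to 42393676 and 42416562 to 42417250). No POU4F3 peak lay on the Pou4f3 gene itself in any of the 4 POU4F3 libraries, whereas an ATOH1 site (42395143 to 42395917) lay on it in the double infection. The strongest ATOH1 peaks on the gene there had a fold enrichment of 3.45 and 4.88, and neither ATOH1 library of Atoh1 cells had a peak on it. Reads of the introduced cDNA can align there too, so this site cannot be read as binding at the gene. The Atoh1 gene (chromosome 6, 64729125 to 64731245) was covered to between 34.3% and 50.02% in all 8 ATAC libraries and had no gained or lost region within 50 kb, so its coverage did not separate Atoh1-infected cells from the others. Near Gfi1, a zinc finger gene that hair cells require (chromosome 5, 107716655 to 107725805), 107723425 to 107723840 on the gene and 107772015 to 107772757 outside it were gained in Atoh1 cells, and the second overlapped an ATOH1 site (107771656 to 107772834). Both Gfi1 regions were also gained in the double infection, while 107749367 to 107749996 was lost there, and the ATOH1 site of Atoh1 cells at 107749245 to 107749821 had no ATOH1 peak in the double infection.

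**Figure D1:**
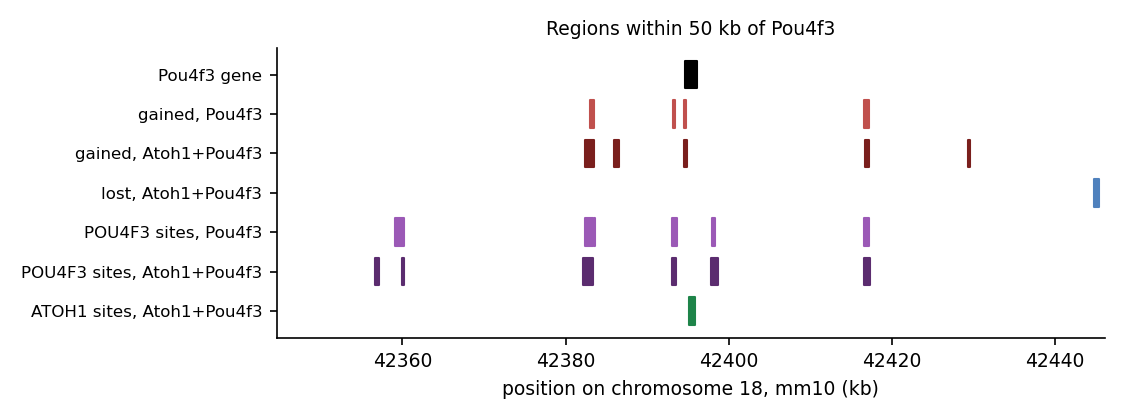
Map of the region within 50 kb of Pou4f3 on chromosome 18; the horizontal axis is position in kb (mm10), and each bar is a gained or lost ATAC region or a CUT&RUN site present in both replicates of the named infection. POU4F3 sites and gained ATAC regions coincide at 42382942 to 42383526 and at 42416632 to 42417247, outside the gene at 42394597 to 42396093.

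Atoh1 alone gained more accessible regions than it lost. In Atoh1 cells, 25886 regions had a peak in both libraries and in neither Gfp library (gained), 8973 had the reverse pattern (lost), and 55146 had peaks in all 4 libraries. When 1 library of each group was put on each side, the 2 mixed splits gave at most 2710 regions. Gains were 9.55 times and losses 3.31 times this count, which holds only noise that differs between replicates. Among the gained regions of highest rank, a region at chromosome 10, 130314130 to 130314952, was the strongest assigned to Neurod4, a neuronal helix-loop-helix gene with 5 gained regions within 50 kb. It had a fold enrichment of 20.6 and 17.9 in the authors' lists, and the gene nearest to it was Tespa1. Other top regions lay near Prep, Atpsckmt and Fat1, and the 2 of highest rank had no gene within 50 kb (chromosome 4, 67423795 to 67424623, and chromosome 12, 78001581 to 78002432). All 10 top regions held an ATOH1 site of Atoh1 cells. Across all gained regions, 39.0% ± 0.450 (SE over chromosomes) held an ATOH1 site and 4.60% ± 0.213 a POU4F3 site of Pou4f3 cells, against 3.21% and 2.91% after a shift of the regions by 20 kb. The top lost regions lay in Cbl and Adgrg6 and near Atp8b4. The exact permutation test of 2 against 2 libraries has 3 splits and cannot give a p below 0.333. With 1 Atoh1 library alone deciding presence, 55536 regions (without replicate 1; 24.5% with an ATOH1 site) and 45404 (without replicate 2) were gained, and with 1 Gfp library deciding, 29663 were lost and 32127 gained (without replicate 1) or 27983 and 31799 (without replicate 2). With lists of equal length, 19740 were gained and 11274 lost.

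Pou4f3 alone also came with gained and lost regions. In Pou4f3 cells 18060 regions were gained and 12694 lost, 7.93 and 5.58 times the highest mixed split of 2276, and 49721 were shared by all 4 libraries. The region of highest rank (chromosome 4, 8398948 to 8399674, no gene within 50 kb) had a fold enrichment of 18.3 and 19.9 in the authors' lists, held sites of both factors and was also open in both Atoh1 libraries. Next came a region near Fgf10, a growth factor gene (chromosome 13, 118834982 to 118835616; 18.8 and 14.5), and others lay in Nsd1 and near Gm10209, Itgb2l and Rbfox1. All 10 top regions held a POU4F3 site of Pou4f3 cells. A region near Prrxl1, a homeobox gene of pain-sensing neurons, reached 13.2 and 11.7 (chromosome 14, 32546533 to 32547206). Of all gained regions, 43.4% ± 0.870 held a POU4F3 site, against 3.37% after the shift. The top lost regions lay near Msc, Grm8 and Hexa. With 1 Pou4f3 library alone, 48532 and 40840 regions were gained (without replicate 1 and replicate 2), of which 23.7% and 28.4% held a POU4F3 site. With 1 Gfp library alone losses outnumbered gains (36281 lost and 22078 gained without Gfp replicate 1, 35319 and 22009 without replicate 2). With 1 Gfp library a loss needs a peak in 1 library while a gain still needs peaks in 2, so the rule itself favours losses. With 1 library on each side gains again exceeded losses (51710 against 43257.5, means over the replicate numbers).

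The double infection gained 40880 regions and lost 19358, which were 23.3 and 11 times the highest mixed split of 1753, and 44296 were shared with Gfp cells. Top gained regions included a region near the matrix gene Dpt (chromosome 1, 164787389 to 164788311; fold enrichment 24.2 and 21.6 in the authors' lists), and others in Cep57l1 and near Gm5965 and Stim2. The first of them, chromosome 18, 15608008 to 15608828, had 24.4 and 23.4 and no gene within 50 kb. In Chrna9, which encodes a nicotinic receptor subunit of hair cells, a region at chromosome 5, 65943114 to 65943910 reached 14.4 and 13.8. Krt20, a keratin gene that marks Merkel cells, had a region at chromosome 11, 99391401 to 99392121 with 14.2 and 11.9. Among the top lost regions was one near Postn, which encodes the matrix protein periostin (chromosome 3, 54413264 to 54414006; 13.5 and 14.4 in the Gfp lists). Others lay near Stxbp5, Nuggc and Camk2d. Of the gained regions 36.0% ± 0.401 held an ATOH1 site, 33.1% ± 0.875 a POU4F3 site and 49.4% ± 0.667 at least 1 of them, against 2.83%, 2.97% and 4.72% after the shift. With 1 library of the double infection alone, 74143 and 72768 regions were gained (without replicate 1 and replicate 2). With 1 Gfp library alone, a rule that favours losses, gains and losses were nearly equal. They were 45630 and 44268 without replicate 1 and 45467 and 42875 without replicate 2. With 1 library on each side, 80456 were gained and 49774.5 lost (means over the replicate numbers). With lists of equal length, 31016 were gained and 22704 lost.

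**Figure D2:**
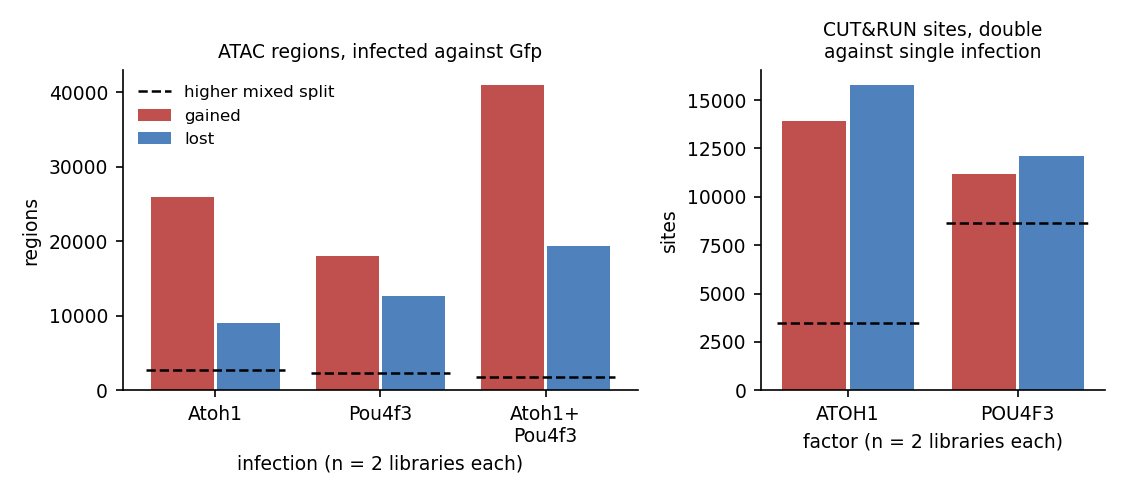
Numbers of gained (red) and lost (blue) ATAC regions of each infection against Gfp cells (left) and of CUT&RUN sites in the double against the single infection (right); the vertical axes are counts and the dashed lines give the higher of the 2 mixed splits of the same libraries. ATAC gains and losses stand at 3.31 to 23.3 times the dashed lines, and POU4F3 sites at 1.29 and 1.40 times.

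Many regions had a called ATAC peak in the double infection and in no other infection. Of the regions gained in the double infection, 13477 (33.0%) had no peak in any of the 4 single-infection libraries, whereas the 24 mixed pairs of libraries from different infections had between 287 and 1323 regions of their own. The other pairs of replicates also had regions seen in them alone, 9544 in Atoh1, 4972 in Gfp and 3466 in Pou4f3 cells. The top regions of this class included regions in Ttc6, Ptk2 and Lonp2. The region in Chrna9 also belonged to this class, and a region near Barhl1, a homeobox gene of hair cells and granule cell precursors, reached a fold enrichment of 13.7 and 10.6 in the authors' lists (chromosome 2, 28952840 to 28953647). An ATOH1 site lay in 33.7% of the class, a POU4F3 site in 30.5% and both in 19.2%, against 2.53%, 2.76% and 1.02% after the shift. At least 1 of them lay in 45.0% of the class, against 4.27% after the shift, so most of its regions held neither. A further 6919 regions (16.9%) were also open in both Atoh1 libraries and neither Pou4f3 library, and 45.9% of these held an ATOH1 site and 11.9% a POU4F3 site. For the 7082 regions (17.3%) open in Pou4f3 cells and not in Atoh1 cells the shares were 32.8% and 63.0%, and for the 2259 regions (5.53%) open in both single infections 51.0% and 40.0%. With 1 library of the double infection alone, the regions without a peak in single infections numbered 35163 and 32481 (without replicate 1 and replicate 2).

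Gains and losses of the infections overlapped. Atoh1 and Pou4f3 cells had 2659 gained regions in common, of 25391 and 17398 in the regions merged over all 8 libraries, and 5284 lost regions, which were 60.0% of the losses of Atoh1 cells. Simulated unchanged groups had 1496 and 1688 in common, with all 8 libraries, Gfp included, drawn from 1 distribution and list sizes not matched to those observed. Independent lists of the observed sizes had 2630 and 1552. The latter numbers rest on the 167963 regions without a peak in either Gfp library for gains, and on the 70045 with peaks in both for losses. The gains in common thus lay at the number for independent lists, whereas the losses in common exceeded both numbers. The double infection shared 10720 gains and 7274 losses with Atoh1 cells (simulated 1489 and 1703; independent lists 6047 and 2352) and 10275 gains and 9919 losses with Pou4f3 cells (simulated 1503 and 1687; independent lists 4144 and 3294). A region near Pou4f3 (chromosome 18, 42444759 to 42445356) was lost in all 3 infections. Part of each excess may come from the shared Gfp libraries, which were not split, since each part would hold 1 library.

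The series asks whether POU4F3 can act as a pioneer factor, a protein that binds closed chromatin and makes it accessible. POU4F3 bound where Gfp cells had no ATAC peak far more often than ATOH1 did. Of the 67774 POU4F3 sites found in both libraries of Pou4f3 cells, 83.2% ± 0.610 (SE over 21 chromosomes) were closed in Gfp cells, against 34.2% ± 0.603 of the 46460 ATOH1 sites in Atoh1 cells. All peaks of each library gave 87.3% ± 0.229 for POU4F3 and 54.7% ± 3.46 for ATOH1 (mean ± SD, n = 2; two-sided exact permutation p = 0.333, the smallest possible). Over sites, which are not replicates, the odds ratio was 9.52 (95% confidence interval 9.26 to 9.79), and the POU4F3 share was higher on 20 of 21 chromosomes. The same sites moved by 20 kb were closed in 94.8% and 90.5% of cases. Within the double infection POU4F3 sites stayed at 81.6% ± 0.618 and ATOH1 sites stood at 55.1% ± 1.05. Per library, ATOH1 peaks were closed in 73.1% ± 1.79 in the double infection and 54.7% ± 3.46 in Atoh1 cells (SD, n = 2; exact permutation p = 0.333), and POU4F3 peaks in 86.7% ± 0.983 and 87.3% ± 0.229 (exact permutation p = 0.667). The ATOH1 share in Atoh1 cells was 57.2% and 52.3% with 1 library alone (without replicate 1 and replicate 2). Without replicate 1 it passed the 55.1% of the double infection, but there sites needed peaks in both libraries, so the rules were unlike. Per library the share was higher in the double infection, as given above.

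Closed ATOH1 sites gained accessibility more often than closed POU4F3 sites. In Atoh1 cells, 64.6% ± 0.597 (SE over chromosomes) of the 15903 closed ATOH1 sites had an ATAC peak in both Atoh1 libraries, against 2.04% after the shift. In Pou4f3 cells the share was 14.5% ± 0.645 of 56391 closed POU4F3 sites, against 0.990% after the shift. Of these sites 2.10% were open in Atoh1 cells, where POU4F3 was not introduced. The odds ratio was 10.8 (95% confidence interval 10.4 to 11.2), with the ATOH1 share higher on 21 of 21 chromosomes. Per library, the shares were 29.1% ± 2.98 for ATOH1 and 8.82% ± 0.471 for POU4F3 (SD, n = 2; exact permutation p = 0.333). In the double infection, 65.7% ± 0.779 of closed ATOH1 sites and 27.6% of closed POU4F3 sites were open. Closed POU4F3 sites that also held an ATOH1 site were open in 64.7% ± 0.831 of 12413 cases, and those without one in 15.4% ± 0.499 of 37766. For closed ATOH1 sites, the shares were 66.5% ± 0.883 with and 64.8% ± 0.915 without a POU4F3 site. Any single CUT&RUN library lowered the opened shares, to 27% and 31.2% for ATOH1 in Atoh1 cells, 9.15% and 8.49% for POU4F3 in Pou4f3 cells, and 31.4% and 25.6% for ATOH1 in the double infection (without replicate 1 and replicate 2).

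**Figure D3:**
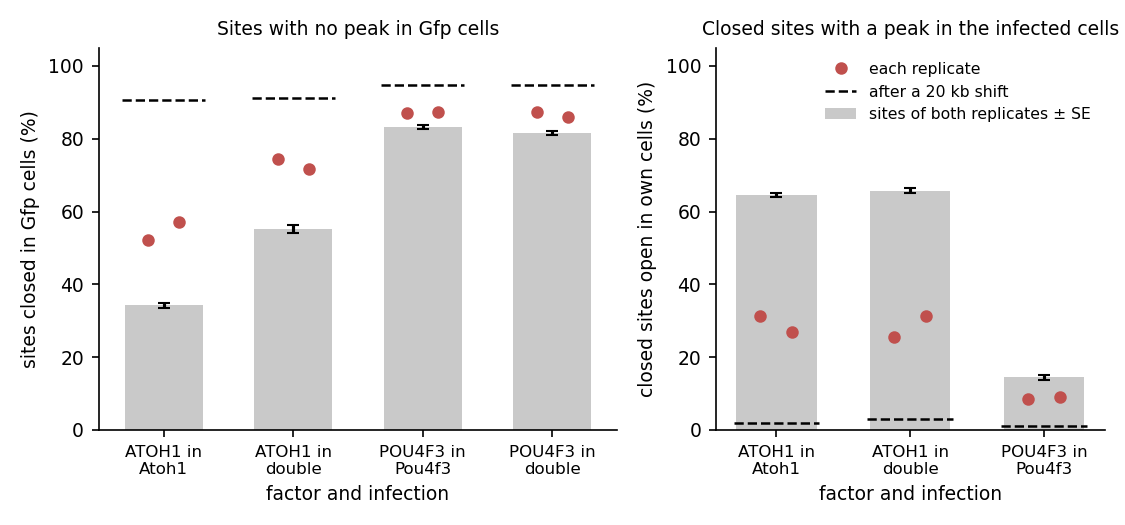
Share in % of CUT&RUN sites without an ATAC peak in Gfp cells (left) and share in % of those sites with an ATAC peak in both libraries of their own infection (right); bars are sites found in both replicates with the SE over chromosomes, points all peaks of each replicate, and dashed lines the sites moved by 20 kb. POU4F3 sites are closed in 83.2% and 81.6% and ATOH1 sites in 34.2% and 55.1%, while 64.6% of closed ATOH1 sites and 14.5% of closed POU4F3 sites are open in the single infections.

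The strength of a site, ranked by the authors' fold enrichment within each list, went with both shares. Among the strongest of 10 equal bins, 70.1% ± 0.743 (SE over chromosomes) of POU4F3 sites in Pou4f3 cells and 12.1% ± 0.572 of ATOH1 sites in Atoh1 cells were closed in Gfp cells, against 89.1% and 47.8% in the weakest bin. Of these closed sites, 46.3% of the POU4F3 sites and 94.7% of the ATOH1 sites were open in their own cells in the strongest bin, and 4.78% and 38.1% in the weakest. In the double infection, the opened share went from 68.4% to 12.6% for POU4F3 and from 94.3% to 41.4% for ATOH1. The POU4F3 site of highest rank gained in the double infection, near the rhodopsin kinase gene Grk1 (chromosome 8, 13424994 to 13425496; fold enrichment 21.2 and 16.9), was closed in Gfp, Atoh1 and Pou4f3 cells and open in both libraries of the double infection.

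**Figure D4:**
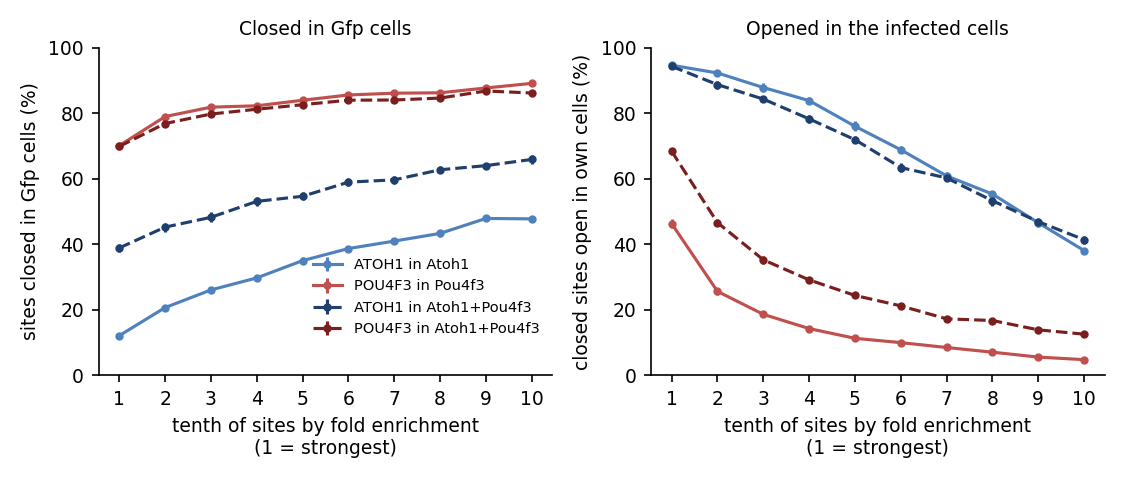
Share in % of sites closed in Gfp cells (left) and share in % of closed sites open in their own cells (right) against bins of fold enrichment from strongest (1) to weakest (10); points are bins of sites found in both replicates, vertical bars the SE over chromosomes, solid lines single and dashed lines the double infection. The opened share goes from 94.7% to 38.1% for ATOH1 in Atoh1 cells and from 46.3% to 4.78% for POU4F3 in Pou4f3 cells.

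ATOH1 was found at different places when Pou4f3 was present. In the double infection ATOH1 gained 13942 sites, lost 15755 and kept 20047 of those in Atoh1 cells, and gains and losses were 4.02 and 4.54 times the highest mixed split of 3470. The top gained ATOH1 sites included one in Slc8a2, a sodium and calcium exchanger gene of neurons (chromosome 7, 16134843 to 16135467; fold enrichment 21.8 and 19.9 in the authors' lists), and others near Glt1d1, Eipr1 and Tlcd3b. The first of them, chromosome 11, 34518067 to 34519110, had 22.5 and 20.5 and no gene within 50 kb. All 10 of these held a POU4F3 site in the double infection. A gained ATOH1 site near Slc17a6, which encodes a vesicular glutamate transporter, reached 22.6 and 14.3 (chromosome 7, 51714819 to 51715785). One in Myt1, a zinc finger gene of neuronal differentiation, reached 17.6 and 15.6 (chromosome 2, 181766693 to 181767352). Among the top lost sites were one near the oncogene Mycn (chromosome 12, 12972712 to 12973609; 20.4 and 14.2) and others in Susd1 and near Mdh1, Nsmce1 and Cpa1.

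Gained ATOH1 sites were closed in Gfp cells in 90.8% ± 0.293 of cases, kept sites in 26.3% ± 0.655 and lost sites in 44.8% ± 0.671 (SE over chromosomes). A POU4F3 site of the double infection lay in 60.6% ± 0.976 of the gained, 39.8% ± 0.955 of the kept and 4.12% ± 0.236 of the lost ATOH1 sites, against 3.98%, 4.07% and 3.03% after a shift by 20 kb. The odds ratio of gained against kept sites was 2.33 (95% confidence interval 2.23 to 2.44; higher on 21 of 21 chromosomes) and of gained against lost sites 35.8 (32.9 to 39.0). POU4F3 sites of Pou4f3 cells, in which Atoh1 was not introduced, lay in 37.1% ± 0.760, 28.6% ± 0.613 and 5.27% ± 0.305 of the gained, kept and lost ATOH1 sites. Regions gained in Pou4f3 cells held an ATOH1 site of Atoh1 cells in 7.25% ± 0.223 of cases (shift 3.17%). They held an ATOH1 site of the double infection in 23.5% ± 0.421 (shift 2.59%), a comparison chosen after a first look at the data. Per library, the shares were 10.5% ± 1.12 and 30.8% ± 5.10 (SD, n = 2; exact permutation p = 0.333). With 1 Pou4f3 ATAC library alone the share for the double infection was 13.4% and 15.4% (without replicate 1 and replicate 2), and without ATOH1 replicate 1 of Atoh1 cells the other was 11.3%. Kept ATOH1 sites lay within 1 kb of a gene end in 32.6% of cases and gained ones in 3.18%. With 1 ATOH1 library of the double infection alone, 44373 and 79447 sites were gained, of which 26.5% and 22.5% held a POU4F3 site of the double infection and 18.2% and 16.4% one of Pou4f3 cells (without replicate 1 and replicate 2). With 1 ATOH1 library of Atoh1 cells alone, 63450 and 48553 sites were lost, and 23720 without replicate 1 of the double infection.

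**Figure D5:**
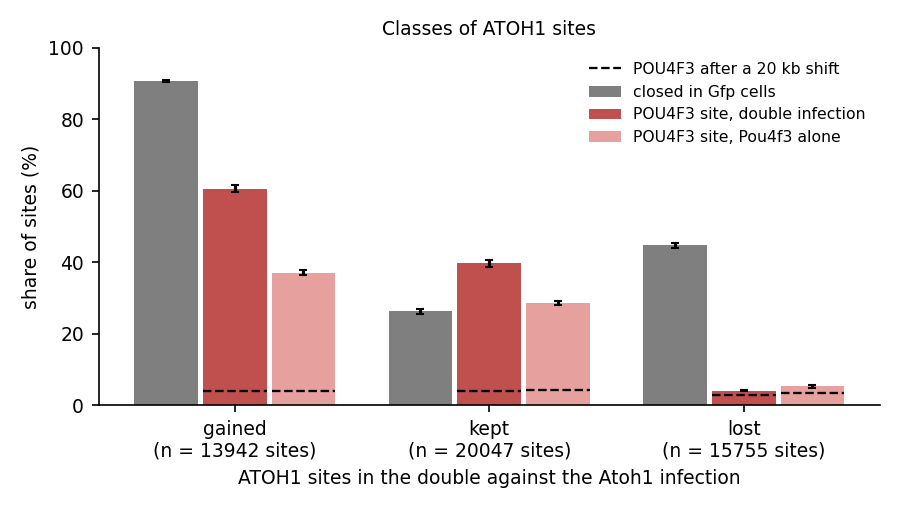
Share in % of ATOH1 sites closed in Gfp cells (grey) or holding a POU4F3 site of the double infection (red) or of Pou4f3 cells (pale red), for sites gained, kept and lost in the double against the Atoh1 infection; error bars are the SE over chromosomes and dashed lines the POU4F3 shares after a 20 kb shift. Gained sites stand at 90.8%, 60.6% and 37.1%, and lost sites at 44.8%, 4.12% and 5.27%.

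POU4F3 sites were also compared between the infections. In the double infection POU4F3 gained 11164 sites, lost 12117 and kept 38815, and gains and losses were 1.29 and 1.40 times the highest mixed split of 8663. With lists of equal length, 8479 sites were gained and 7688 lost against a highest mixed split of 3636. With stricter peaks, 5188 were gained and 6679 lost against 4907, and with sharing by summits 12791 and 14726 against 10645, so gains barely exceeded replicate noise under stricter peaks and the margin depended on the setting. Top gained POU4F3 sites lay near Grk1 and Rtp4 and in Gm10130, Ptprn2, Pacs1 and Mab21l3, and top lost ones in Elfn2, Rnf157 and Fam98a. An ATOH1 site of the double infection lay in 42.2% ± 0.994 (SE over chromosomes) of gained, 29.6% ± 0.684 of kept and 2.39% ± 0.225 of lost POU4F3 sites, against 2.33%, 2.93% and 1.67% after the shift. The odds ratio of gained against kept was 1.73 (95% confidence interval 1.66 to 1.81). With 1 POU4F3 library of the double infection alone, 47964 and 57869 sites were gained (without replicate 1 and replicate 2) and 21862 and 18381 lost. With 1 of Pou4f3 cells alone 50348 and 61273 were lost, and 19112 gained without replicate 1.

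Genes of hair cells, neurons and other cell types were then counted by whether a gained or lost region lay within 50 kb of the gene. In the double infection 36 of 40 hair cell genes had a gained region (35.4 for genes with as many ATAC regions around them) and 21 of 26 Merkel cell genes (21.2). The counts were 25 of 26 pan-neuronal genes (21.9), 16 of 21 sensory neuron genes (18.1), 21 of 22 Notch pathway genes (20.3), 19 of 20 granule cell precursor genes (18) and 14 of 18 intestinal secretory genes (16.1). Of the lists for other cell types, 22 of 24 skeletal muscle (21.8), 16 of 18 epithelial (15.5), 14 of 16 macrophage (13.8), 15 of 16 endothelial (14.3) and 24 of 28 fibroblast genes (25.5) had one, as did 19 of 20 cell cycle (17.6), 15 of 18 interferon response (15.6) and 14 of 18 housekeeping genes (15.8). Named members were Barhl1, Myt1 and Insm1, a zinc finger gene of neuronal and endocrine precursors, with 7 regions each, Slc17a6 with 8, and Ntrk2, the receptor gene for brain-derived neurotrophic factor, with 9. In Atoh1 cells, all 24 skeletal muscle genes had a gained region (19.5; exact p = 0.00919), among them Myog with 7 and Tnnc1, and all 16 endothelial genes (12.7; exact p = 0.0380). There 23 of 26 pan-neuronal genes (18.8), among them Neurod4, Nhlh1 and Gap43, and 20 of 22 Notch pathway genes (18.4), among them the ligand genes Jag1 and Dll1, had one. In Pou4f3 cells, 15 of 21 sensory neuron genes (13.6), 27 of 40 hair cell genes (26.6) and 16 of 26 Merkel cell genes (14.4) had one, among them Prrxl1, Xirp2 and Cplx2.

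None of the 165 tests of 15 lists in 11 comparisons passed at an adjusted p of 0.05 (exact hypergeometric test within bins of the number of ATAC regions, two-sided, Benjamini-Hochberg; lowest adjusted p = 0.577), and 9 had an unadjusted p under 0.05. Beyond the 2 lists above, these included 18 of 26 pan-neuronal genes with a region that had a peak only in the double infection (12.8; exact p = 0.0415). They also included 24 of 28 fibroblast genes with a region lost there (19.3; exact p = 0.0488). Of the fibroblast genes, 25 of 28 had a lost ATOH1 site (18.9; exact p = 0.0102) and 18 of 28 a lost POU4F3 site (11.2; exact p = 0.0109), as did 13 of 21 sensory neuron genes (7.83; exact p = 0.0230). Below the number for matched genes were 2 of 18 interferon response genes (6.62; exact p = 0.0255) and 4 of 24 skeletal muscle genes (9.14; exact p = 0.0336) with a gained POU4F3 site. A gained region lay near 75.0% of all 21887 protein-coding genes in the double infection, so counts of members had little room above the number for matched genes. Even all 24 skeletal muscle genes with a region gained in Atoh1 cells, the highest count possible, had an adjusted p of 0.577 (exact test). Where regions are this common, the lack of a passing test is thus no evidence against an excess. Counting the regions themselves, a test added after the data were seen, 3 tests of 2 lists passed. Pan-neuronal genes had 102 gained regions in the double infection (65.1 in random lists, 1.57 times; adjusted permutation p = 0.0176). Fibroblast genes had 79 lost regions there (42.5, 1.86 times; adjusted permutation p = 0.0033), with examples at Postn, Acta2, S100a4 and Prrx1. They also had 78 lost ATOH1 sites (39.5, 1.98 times; adjusted permutation p = 0.0033), with examples at Col5a1, Ddr2 and S100a4. The unadjusted permutation p of these sites, 2e-05, is the smallest that 100000 random lists can give. Random lists were matched on ATAC regions of any library, not on Gfp regions or on ATOH1 sites of Atoh1 cells. More regions or sites that could be lost near fibroblast genes are thus not excluded. Assigning each region to its nearest gene, 19 of 24 skeletal muscle genes had a region gained in Atoh1 cells (10.4; adjusted p = 0.0128, exact test). Without ATOH1 replicate 1 of Atoh1 cells, 31 of 40 hair cell genes had a lost ATOH1 site, fewer than the 37.7 of matched genes (adjusted p = 0.0204, exact test).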

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

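Of the tests in this part, only the one against POU4F3 sites of Pou4f3 cells was chosen after its result had been seen. Peaks on contigs outside the chromosomes entered no comparison, and every library held some, between 65 and 113 lines in ATAC. With no antibody-free control used here, those of CUT&RUN have no background level to be set against: 140 and 116 for ATOH1 in Atoh1 cells, 142 and 93 for ATOH1 in the double infection, 157 and 145 for POU4F3 in Pou4f3 cells, and 134 and 139 for POU4F3 in the double infection.

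POU4F3 sites lay far more often than ATOH1 sites where Gfp cells had no ATAC peak. Weak peaks, or false ones of low fold enrichment, in the POU4F3 lists would make the gap vanish among strong peaks, yet in the strongest of 10 bins it was 58.0 points (SE 0.938; 70.1% against 12.1%). False peaks of high fold enrichment cannot be told apart this way, as no antibody-free control was used here. Longer POU4F3 lists would make it vanish with lists of equal length, where it was 49.4 points (SE 0.804; 81.5% against 32.1%). A candidate biological explanation is that POU4F3 in these fibroblasts binds closed chromatin more often than ATOH1 does. False POU4F3 peaks of high fold enrichment, different antibodies and unlike levels of the introduced proteins stay open as untested.

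Closed POU4F3 sites had an ATAC peak in their own cells less often than closed ATOH1 sites. Weak POU4F3 peaks as the whole cause are argued against by a gap of 48.4 points in the strongest bin (SE 1.44; 94.7% against 46.3%). Fewer ATAC peaks in Pou4f3 cells are argued against by a gap of 46.6 points with lists of equal length (SE 0.948; 65% against 18.4%). The opened share of POU4F3 fell to 4.78% in the weakest bin, so weak peaks may account for part of its low overall share. Binding of closed sites by POU4F3 may still often leave them without a detected peak, which is a hypothesis found and tested on the same libraries. Accessibility below the detection of a peak, false POU4F3 peaks of high fold enrichment, and differences in depth stay open.

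ATOH1 sites gained in the double infection often held a POU4F3 site. CUT&RUN background in newly opened chromatin was examined at gained ATOH1 sites without an ATAC peak in either library of the double infection. There the POU4F3 share was 13.7 times that after a 20 kb shift (55.0% against 4.01%). This argues only against background confined to regions with a called ATAC peak. Background in chromatin opened below the detection of a peak stays open, since a missing peak need not mean closed chromatin. Noise shared by libraries of the same cells, as the only source, is argued against by POU4F3 sites of Pou4f3 cells. Their share was 9.14 times the shifted one (37.1% against 4.06%). It was lower than the 60.6% for POU4F3 sites of the double infection, so shared noise at part of the sites stays open. A candidate explanation, not tested itself, is that POU4F3 directs part of ATOH1 to its own sites. Regions that give peaks with any antibody in all cells cannot be gained ATOH1 sites by definition. The POU4F3 shares of kept and gained sites (39.8% against 60.6%) therefore do not test them. Such peaks arising only where Pou4f3 was introduced stay open, as no antibody-free control was used here.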

How the results depend on the processing

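Among the values in this part, the count of regions per gene list was chosen after seeing the data, as were the shares of regions gained in single infections that hold a site. Of 260 alternative values of 26 results, 107 stayed within the spread between replicates or 1.5 times the count and 153 moved. Single counts and shares cannot change sign, so only orders between them could turn. The motif tests were not run, since no genome sequence was used here. Depth is unknown, so a missing peak may be a shallow library, and the counts moved with presence set by 1 library (55536 for gains in Atoh1 cells). Both replicates of the group that must hold the peak moved its counts by over 1.5 times, by construction. POU4F3 stayed above ATOH1 in the closed share in 11 of 11 settings (26.0 to 53.8 points) and ATOH1 above POU4F3 in the opened share in 15 of 15 (12.5 to 60.4 points). The closed share of ATOH1 was higher in the double than in the Atoh1 infection in 10 of 11, the exception being without ATOH1 replicate 1 of Atoh1 cells (-2.05 points). There all peaks of 1 library were set against sites of both libraries. Under the block the share stayed higher in the double infection (75.4% against 58.6%). For the opened share of ATOH1 the order held in only 6 of 15. Gains were higher in the double than in the Atoh1 infection in 9 of 11 settings, the exceptions being 55536 and 45404 in Atoh1 cells without Atoh1 replicate 1 or 2 against 40880. They were higher in Atoh1 than in Pou4f3 cells in 9 of 11, the exceptions being 48532 and 40840 in Pou4f3 cells without Pou4f3 replicate 1 or 2 against 25886. In all these exceptions 1 library set presence on one side and 2 libraries on the other, so the rules were unlike. Under the block, gains kept both orders (80456, 59834.5 and 51710 in the double, Atoh1 and Pou4f3 infections). Gains exceeded losses in Pou4f3 cells in 7 of 9, the exceptions being without either Gfp replicate (-14203 and -13310). There a loss needs a peak in 1 library and a gain in 2, which favours losses, as leaving out a Pou4f3 replicate favours gains. More ATOH1 sites were lost than gained in 5 of 8, the exceptions being the block and either ATOH1 replicate of the double infection left out. Leaving out a replicate of the double infection favours gains, and leaving out one of Atoh1 cells favours losses. The causes below were not tested, except that stricter peaks leave fewer regions.

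With a −log10 q of at least 5, gains were 17210, 9637 and 22848 and losses 4087, 6011 and 9857 in the Atoh1, Pou4f3 and double infections (25886, 18060 and 40880; 8973, 12694 and 19358 as reported), and the highest mixed splits 864, 780 and 744. Double-only regions were 8077 (13477 as reported). ATOH1 sites gained were 7960 and lost 9398 (13942 and 15755; mixed split 1193), and POU4F3 sites 5188 and 6679 (11164 and 12117; mixed split 4907). Closed shares were 85.2% for POU4F3 in Pou4f3 cells, 83.6% for POU4F3 and 57.1% for ATOH1 in the double infection, and the opened share of ATOH1 in Atoh1 cells was 70.5%. The share of gained ATOH1 sites with a POU4F3 site of Pou4f3 cells was 33.1%. With lists of equal length, 8479 POU4F3 sites were gained and 7688 lost, against a mixed split of 3636 (8663 as reported). There POU4F3 was closed in 81.5% and 80.2%, 18.4% of closed POU4F3 sites opened in Pou4f3 cells, and gained ATOH1 sites held POU4F3 of the double infection in 57.0% and of Pou4f3 cells in 32.8%. With sharing by summits, closed shares were 42.6% and 60.9% for ATOH1 and 87.3% and 85.5% for POU4F3 (single, double). By summits, opened shares were 44.6% and 53.8% for ATOH1 and 11.2% for POU4F3, gained ATOH1 sites held POU4F3 in 45.9% and 26.6%, and 39.7% of gained regions held a site. Without sites of the other factor, POU4F3 was closed in 91.3% and 91.8%. With the nearest gene 1 gene list test passed and with regions counted 3 did, 2 of them of fibroblast genes, against 0.

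Same-numbered libraries of different groups were about as alike as differently numbered ones (Jaccard 0.413 and 0.413 in ATAC, 0.143 and 0.140 in CUT&RUN). Presence of peaks thus showed no pairing by number, which does not exclude a pairing in the design. With the replicate number as a block, each value is a mean over pairs of single libraries: gains were 59834.5, 51710 and 80456, losses 35479, 43257.5 and 49774.5, and double-only regions 41821. Under the block, ATOH1 sites were 67051 gained and 64779.5 lost, and POU4F3 sites 65670.5 and 71095.5. Under the block, closed shares were 58.6% and 75.4% for ATOH1 and 88.7% and 88.1% for POU4F3, opened shares 37.5% and 34.0% for ATOH1 and 12.6% for POU4F3, gained ATOH1 sites held POU4F3 in 29.9% and 21.5%, and 43.6% of gained regions held a site.

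Leaving out each library in turn, gains ranged from 31799 to 55536 (highest without Atoh1 replicate 1), 22009 to 48532 (Pou4f3 replicate 1) and 45467 to 74143 (double replicate 1), losses from 11602 to 29663, 16747 to 36281 and 22418 to 44268 (each without Gfp replicate 1), and double-only regions from 13659 to 35163. ATOH1 sites gained ranged from 15789 to 79447 and lost from 18210 to 63450, and POU4F3 sites from 14667 to 57869 and 18381 to 61273. Closed shares ranged from 38.3% to 57.2% and 58.2% to 74.3% for ATOH1 and 84.8% to 87.5% and 83.3% to 87.4% for POU4F3, and opened shares from 27% to 74.9% and 25.6% to 71.9% for ATOH1 and 8.49% to 18.6% for POU4F3. Gained ATOH1 sites held POU4F3 in 22.5% to 70.3% (double) and 16.4% to 46.5% (Pou4f3 cells), gained regions a site in 35.5% to 60.7%, and 0 to 1 gene list test passed.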

Other observations

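The counts of ATOH1 sites in regions lost with Pou4f3 were chosen after the data were seen, and the test of the hypothesis on lost regions before. Of the 12694 regions lost in Pou4f3 cells, 14.4% ± 0.351 (SE over chromosomes) held an ATOH1 site of Atoh1 cells, against 2.84% after a 20 kb shift, and 3.08% ± 0.173 an ATOH1 site of the double infection, against 2.09%. Regions kept in Pou4f3 cells held such sites more often, in 44.5% and 28.3% of cases. Among ATOH1 sites, those lost in the double infection were open in Atoh1 cells in 77.7% of cases and in the double infection in 39.0%. Kept ATAC regions lay within 1 kb of a gene end in 26.1%, 28.6% and 31.4% of cases in the Atoh1, Pou4f3 and double infections, against 4.15%, 4.42% and 3.69% of gained and 4.02%, 3.4% and 3.79% of lost regions. POU4F3 sites lay there in 7.40% of cases in Pou4f3 cells and ATOH1 sites in 23.5% in Atoh1 cells, against 3.24% and 6.07% after the shift.

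The hypothesis that the infected factors sit at the regions that are lost was tested and not borne out. The share of lost regions with a site of the infected factor was at most 0.0953 times that of kept regions in the 3 infections: 1.36% against 45.6% for Atoh1, 1.69% against 17.8% for Pou4f3, and in the double infection 0.589% against 33.1% for ATOH1 and 1.30% against 20.2% for POU4F3. These shares also lay below those after the shift (3.23%, 2.95%, 2.60% and 2.79%). Sites were measured after the loss, so binding before it is not excluded, and lost regions were narrower than kept ones (medians of 402, 410 and 450 bp against 779, 766 and 796 bp).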
